A study of Mus musculus with 6 samples.

How the data were processed

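RNA was measured in 6 mouse livers, 3 from obese mice given HA (hippuric acid, the glycine conjugate of benzoic acid) and 3 given PBS (phosphate-buffered saline). Groups were taken from the treatment label of each sample. Per the series design text, HA was injected into the abdomen at 60 mg/kg, 2 times per week, for 5 weeks; whether PBS was given on the same schedule is not stated. Nothing in the labels says that the livers came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. Per the labels' protocols, RNA was extracted with TRIzol and checked on a Bioanalyzer. The protocols name 2 library kits, VAHTS Universal V6 and TruSeq Stranded Total, without saying which was used for which library.

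The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the depth of the library) for 16638 genes, with 1 column per sample. The unit was worked out from the values, because the header names samples only. Per the submitters' processing notes, Trimmomatic (a read trimmer) and HISAT2 (an aligner) were used with the mouse build GRCm39, and no versions are given. The counter, the annotation and any filter on genes are not given in the sources used here, nor is the use of strand. No coordinates are printed because the annotation in hand belongs to another build. Genes are named by the symbols of the table. Genes with near-identical copies, such as the globins, Hamp and Hamp2, the Mup, Serpina1 and Nat8 families, are uncertain, since fragments could have been split between copies.

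The FPKM values still held the depth. Ratios of low values between libraries were ratios of whole numbers, which gave the library totals, and from these the whole fragments and the length of each gene. All 99828 values (100%) came out whole within 0.0001. The totals rest on the smallest whole numbers that fit, so a common factor could remain. They were 39043440, 39908844 and 38209590 fragments for PBS replicates 1 to 3 and 39349601, 38208626 and 37921444 for HA replicates 1 to 3, and the genes in the table held 99.84 to 99.87% of them. In simulated data the recovery was exact for 99.05% of 3897 genes. Fragments are not independent molecules, and these depths describe counting error only. A chi-square test of the recovered fragments gave at least 33.5 per degree of freedom for every pair of libraries, so no library was a copy of another.

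Tests were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with treatment as the only term, for the 10745 genes with a mean of at least 0.5 FPKM over the 6 libraries. The variance followed a trend on expression and robust fitting was off; the wording fixed beforehand could also be read as no trend, which is among the alternatives. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds of means are on the FPKM scale. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Before the data were examined, 40 gene lists (pathways, cell types, signs of handling) were fixed and tested with camera (limma) at a preset inter-gene correlation of 0.01, for the 38 lists with at least 3 measured members, with Benjamini-Hochberg adjustment over lists. The members of the list of mitochondrial genes were matched to the symbols of the table after it was seen. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so single values were tested only in the model across genes.

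Genes were named by a rule fixed at the same time. It took Cd36, Ugdh and Foxk1, the genes of the series title. It took the 10 largest rises and 10 largest falls among genes past the threshold whose 3 values in one group all lay beyond those of the other and whose higher mean was at least 1 FPKM. Unnamed models and pseudogenes were skipped, which removed 0 rises and 1 fall. It took up to 4 members of each list described, by smallest unadjusted p, and Xist and 4 Y-linked genes as a check of sex. Some genes that the rule or the lists would name are not reported here, which leaves 18 genes named by size of change. Genes named outside the rule are said to be so. After the data were seen, 6 more lists were written for the closing section: BMP-SMAD targets, iron storage and uptake, globins, platelets, adrenal gland and skeletal muscle. The BMP-SMAD targets were all those looked up, chosen before their values were seen. The members of the other lists were chosen with values in view, except 9 adrenal and muscle genes, and the test of the adrenal and muscle lists used only those 9.

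The model was tested on simulated data. In 10743 simulated genes of HA against PBS, with dispersions taken as medians over bins of expression, it called 31.3% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. It also called 5 unchanged genes, 3.3% of its calls. Simulated genes of a bin shared the same dispersion, which leaves out genes more variable than the median. The shares called may thus be too high for the real data, and a gene not called there may still be changed. The list test called the 1 shifted list and 0 of 50 random lists. Genes were simulated independently, so this does not measure false calls in lists whose members vary together. In the real lists the estimated correlation reached 0.924, for cholesterol synthesis. Alternatives fixed beforehand were no filter, a filter at a mean of 1 FPKM, a pseudocount of 0.1, median centring, a replicate block, leaving out each library, a log2 fold change above 1, and an estimated correlation in camera. Alternatives chosen after seeing the data were limma-voom on the recovered fragments with library totals or median-ratio depths, limma with no trend, and FPKM rescaled to the fragments outside Alb. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.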

Results

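Liver RNA of obese mice was compared between 3 livers after HA and 3 after PBS. Depth was even, at 37921444 to 39908844 fragments per library. Xist was at or below 0.00883 FPKM in all 6 libraries, and Ddx3y lay between 15.8 and 28.4 FPKM. Uty was 1.53 to 2.63 FPKM, Kdm5d 2.28 to 3.25 FPKM and Eif2s3y 5.59 to 6.74 FPKM, so all 6 libraries carried the pattern of male mice. The first principal component held 43.2% of the variance and separated the groups, and the next held 25.9% and set HA replicate 2 apart from HA replicate 1. Albumin (Alb), the main plasma protein made by hepatocytes, took 7.53 to 9.82% of the fragments in the PBS libraries and 12.5 to 14.7% in the HA libraries. Transcripts of adrenal gland and skeletal muscle were higher in PBS replicate 1 than in the other 5 libraries, which held some at lower values. Hsd3b1 was at 19.1 FPKM against 0, and Star at 14.0 against 0.123 to 0.248 FPKM. Acta1 was at 14.9 against at most 0.150 FPKM, and Mylpf at 7.07 against 0.248 to 0.713 FPKM. These 4 genes were chosen after their values were seen.

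The comparison of HA with PBS asks which liver transcripts differ after hippuric acid. Hepcidin (Hamp), the liver hormone that limits iron release into blood, fell from 1367 ± 333 FPKM to 7.35 ± 5.78 FPKM (mean ± SD, n = 3 per group), 186-fold, or 310-fold without HA replicate 2. Tff3, a secreted trefoil peptide, rose from 0.562 ± 0.379 to 58.7 ± 29.4 FPKM, 104-fold, or 164-fold without PBS replicate 3. The globins Hba-a1, Hba-a2 and Hbb-bt rose 3.98-fold, 3.34-fold and 5.01-fold. Several major urinary protein genes and the lipid enzymes Mogat1 and Cyp4a12a fell. In all, 31 genes were higher and 55 lower with HA (limma, Benjamini-Hochberg adjusted), and the groups did not overlap in any of the 86. Of all genes tested, 25.6% had groups that did not overlap, against 10% by chance. These were mostly lower with HA, 2059 genes against 695 higher, in FPKM with no further scaling. The median log2 change of all tested genes was -0.064, and 0.003 after rescaling to the fragments outside Alb. The excess of falls may thus depend on the scaling.

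Among the rises, Serpina1e, a member of the alpha-1-antitrypsin family, went from 237 ± 71.1 to 1662 ± 348 FPKM (adjusted p = 0.00678). Enho, which encodes the secreted peptide adropin, rose 5.05-fold, the magnesium transporter gene Nipal1 8.91-fold (14.0-fold without PBS replicate 3) and the metallothionein gene Mt2 3.71-fold. Log2 fold changes of the named rises ran from 1.70 (Hba-a2, SE 0.22) to 5.13 (Tff3, SE 0.41), with adjusted p between 0.00678 and 0.0424. Among the falls, Hamp changed by -7.63 on the log2 scale (SE 0.55, adjusted p = 0.00608) and its copy Hamp2 by -4.39 (SE 0.67, adjusted p = 0.0425). Cyp4a12a, a fatty acid omega-hydroxylase, fell 6.17-fold to 5.29 ± 4.01 FPKM, or 10.6-fold without HA replicate 2. Mup15, Mup17 and Mup12 fell 9.29-fold, 6.42-fold and 4.32-fold. Nat8f5 fell 12.4-fold to 0.575 ± 0.453 FPKM, or 22.7-fold without HA replicate 3, and Mogat1, which makes diacylglycerol, fell 8.13-fold. Serpinb1a, an inhibitor of neutrophil proteases, fell 4.02-fold from 10.8 ± 0.727 FPKM, and Acss3, a mitochondrial acyl-CoA synthetase, fell 3.44-fold. Globin, Hamp, Mup, Serpina1 and Nat8 values are uncertain where copies share fragments.

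**Figure D1:**
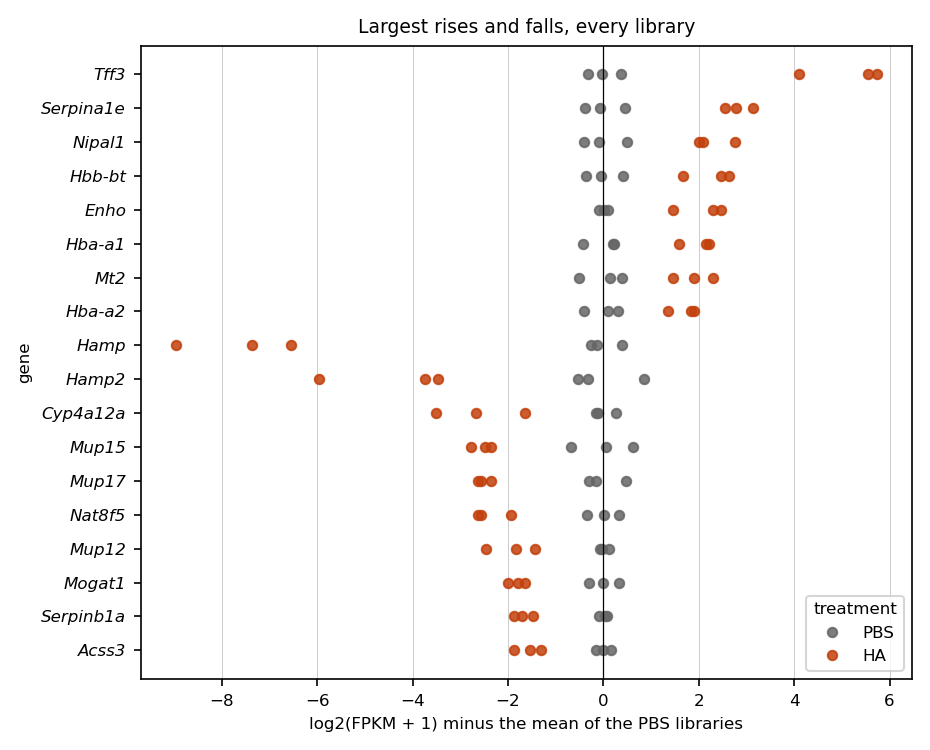
Log2(FPKM + 1) of 18 genes among the largest rises and falls, 1 row per gene, as the difference from the mean of the PBS libraries; each point is 1 library, grey for PBS and orange for HA. The groups do not overlap for any of the 18 genes, and Hamp lies farthest to the left.

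The number of genes called was not stable. Without PBS replicate 1, 2 or 3 in turn, limma called 3, 1 and 5 genes higher and 4, 7 and 6 lower; without HA replicate 1, 2 or 3 it called 17, 46 and 6 higher and 17, 69 and 19 lower, and Hamp, Mup17 and Serpinb1a were the 3 of the 18 named genes that passed in all 6 of these fits. The balance moved with the scaling, to 36 higher and 32 lower after median centring, 28 and 19 with voom on median-ratio depths and 33 and 24 outside Alb. Tff3 did not pass with voom on recovered fragments (adjusted p = 0.0617) or with voom on median-ratio depths (adjusted p = 0.0701), and Hamp2 and Mup15 also lost their calls in both. Hamp2 and Cyp4a12a lost theirs with a pseudocount of 0.1, after median centring and outside Alb. With no filter 10 of the 18 named genes did not pass, and with a replicate block 9 did not.

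The series title names Ugdh, which makes UDP-glucuronate, Foxk1, a transcription factor, and Cd36, a fatty acid translocase, and asks whether hippuric acid acts through them. Cd36 fell from 66.5 ± 4.07 to 32.4 ± 6.32 FPKM (n = 3 per group), a log2 fold change of -1.03 (SE 0.15, limma adjusted p = 0.0411). Ugdh was 76.4 ± 3.75 FPKM with PBS and 48.9 ± 12.4 FPKM with HA. Its log2 fold change was -0.66 (SE 0.18), with all 3 HA values below all 3 PBS values, and it did not pass over all genes tested (adjusted p = 0.130). Foxk1 was 2.92 ± 0.370 and 2.35 ± 0.313 FPKM, and its groups overlapped (log2 fold change -0.23, SE 0.12, adjusted p = 0.360). Adjusted over the list alone, Cd36 (adjusted p = 0.000467) and Ugdh (adjusted p = 0.0106) passed and Foxk1 (adjusted p = 0.0935) did not; since the title comes from the study itself, this is not independent evidence. As a list of 3, they were lower in camera (adjusted p = 0.00916, and 0.264 with an estimated correlation), which is not independent evidence either. The call of Cd36 was lost without PBS replicate 1, 2 or 3 or HA replicate 1 (adjusted p = 0.152, 0.137, 0.140 and 0.0818) and kept without HA replicate 2 or 3; over all alternatives its adjusted p ran from 0.0287 to 0.152. It was also lost with no filter (adjusted p = 0.0854), with a replicate block (adjusted p = 0.118), with voom on median-ratio depths (adjusted p = 0.0558) and outside Alb (adjusted p = 0.0568).

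**Figure D2:**
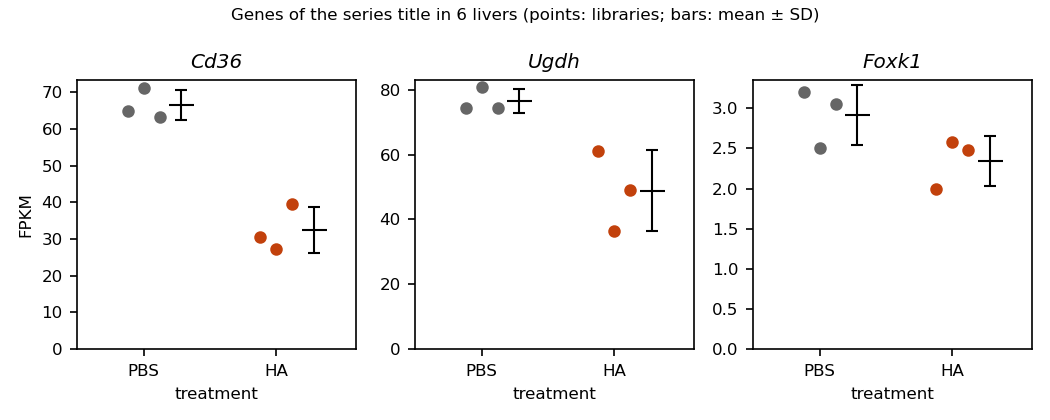
FPKM of Cd36, Ugdh and Foxk1 in each library (points) by treatment, with the mean and SD of each group beside them; each panel has its own linear axis from 0. The HA values of Cd36 (27.2 to 39.5 FPKM) and Ugdh lie below all PBS values, and those of Foxk1 overlap.

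The lists of PPARg-driven steatosis and of triglyceride synthesis were lower in camera with a preset correlation, and few of their members passed over all genes. These lists share Mogat1, Cidea, Cidec, Plin2 and Plin4, so they are not separate results. Of 13 measured members of the list of PPARg-driven steatosis genes, 2 fell (Mogat1 and Cd36) and 11 did not pass; adjusted over the list alone, 10 fell and 1 rose. Fitm1, which helps form lipid droplets, was 54.1 ± 3.14 and 16.6 ± 8.40 FPKM with PBS and HA, and Pparg itself 6.71 ± 0.760 and 3.62 ± 0.887 FPKM, neither past the threshold over all genes. The list median was -1.03 (camera adjusted p = 0.000581; adjusted p = 0.264 with an estimated correlation). Of 20 measured genes of triglyceride synthesis and lipid droplets, 1 (Mogat1 again) fell over all genes and 4 fell adjusted over the list alone. The median of that list was -0.43 (camera adjusted p = 0.000912, and 0.264 with an estimated correlation). Agpat2, Plin2 and Plin4 were among those 4, at 74.9 ± 9.08, 95.1 ± 13.6 and 3.47 ± 2.42 FPKM with HA against 112 ± 12.7, 150 ± 24.1 and 9.83 ± 1.26 FPKM with PBS.

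Of 32 genes of fatty acid oxidation and ketogenesis, 30 had a negative log2 fold change, 2 fell over all genes and 14 adjusted over the list alone. Among them Acaa1b, a peroxisomal enzyme of beta-oxidation, fell from 747 ± 88.5 to 346 ± 60.6 FPKM. Hadh and Acads, of mitochondrial beta-oxidation, were 291 ± 15.4 and 90.2 ± 10.4 FPKM with PBS and 194 ± 18.4 and 63.9 ± 5.54 FPKM with HA and passed adjusted over the list alone. The list median was -0.55 (camera adjusted p = 2.63e-06; adjusted p = 0.388 with an estimated correlation), and -0.30 without HA replicate 1, with the call kept (adjusted p = 0.000152). All 28 measured genes of the nuclear respiratory chain had a negative log2 fold change with a median of -0.24 (camera adjusted p = 4.69e-06, and 0.388 with an estimated correlation). Of these, 0 passed over all genes, and 1, Ndufb3, adjusted over the list alone. Members of both lists varied together (estimated correlation 0.455 and 0.461), and the median of all genes tested was itself -0.064. A shared sign is thus weaker evidence than the counts of negative members. The mitochondrially encoded transcripts did not pass (adjusted p = 0.818), but were lower without PBS replicate 2 (adjusted p = 0.0407). Mgll and Lipc, which cleave lipids, were the 2 of 17 genes of lipolysis and VLDL export that fell over all genes, and adjusted over the list alone 4 fell and 2 rose. That list had a median of -0.28 (adjusted p = 0.0379; adjusted p = 0.388 with an estimated correlation), lost without PBS replicate 3 (adjusted p = 0.0927) or HA replicate 1 (adjusted p = 0.172) and with a filter at a mean of 1 FPKM (adjusted p = 0.0650).

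Cholesterol synthesis genes were higher as a list, unevenly between HA livers. The median of the 24 members was 0.70 (camera adjusted p = 6.02e-06; adjusted p = 0.469 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Sqle, a rate-limiting enzyme of the pathway, was 1.14 to 2.54 FPKM with PBS and 38.7, 0.933 and 17.7 FPKM in HA replicates 1, 2 and 3. Without HA replicate 1 the median was 0.13 and the call was lost (adjusted p = 0.0820), and without HA replicate 2 it was 1.25. De novo lipogenesis did not pass (median 0.08, adjusted p = 0.101), and its direction depended on single libraries. It was lower without HA replicate 1 (median -0.35, adjusted p = 0.0205). It was higher without HA replicate 2 (0.40, adjusted p = 0.000923), HA replicate 3 (0.28, adjusted p = 0.0130) or PBS replicate 1 (0.25, adjusted p = 0.0299). Me1 had the smallest p of that list, at 26.3 ± 0.724 and 14.7 ± 5.18 FPKM. Fatty acid uptake and binding did not pass either (adjusted p = 0.584), with a median of -0.22, a mean of 0.09 and a test direction that was down; over all genes 1 member, Cd36, fell, and adjusted over the list alone 5 fell and 3 rose, Acsl4 among the rises.

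Lists of conjugation and drug metabolism were lower in camera with a preset correlation, with at most 1 member of each past the threshold over all genes. Of 19 measured genes of UDP-glucuronate and glucuronidation, Ugt2b1 fell over all genes, from 146 ± 9.60 to 75.2 ± 1.81 FPKM (limma adjusted p = 0.0161), and 12 fell adjusted over the list alone, with a median of -0.56 (camera adjusted p = 6.02e-06; adjusted p = 0.264 with an estimated correlation). Of 20 CAR, PXR and AhR targets, Gstt3 fell over all genes and 7 adjusted over the list alone, with a median of -0.55 (adjusted p = 0.00550; adjusted p = 0.264 with an estimated correlation; adjusted p = 0.0516 without PBS replicate 3). Of 22 genes of NRF2 and oxidative stress, Aox1 fell over all genes and 9 adjusted over the list alone, among them the glutathione peroxidases Gpx1 and Gpx4, with a median of -0.45 (adjusted p = 4.69e-06; adjusted p = 0.264 with an estimated correlation). Glyat, which joins glycine to benzoyl-CoA to make hippurate, was 199 ± 12.7 FPKM with PBS and 138 ± 14.3 FPKM with HA. It was 1 of 3 members of the list of glycine conjugation and glycine metabolism that fell adjusted over the list alone; 0 of 16 passed over all genes. The list median was -0.25 (adjusted p = 0.0358; adjusted p = 0.264 with an estimated correlation), and the call was lost without PBS replicate 2 or 3 or HA replicate 2 or 3 (adjusted p = 0.0839, 0.0689, 0.0789 and 0.0708). It was also lost with a filter at a mean of 1 FPKM (adjusted p = 0.0618) and with a replicate block (adjusted p = 0.0521).

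Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, fell from 195 ± 47.5 to 68.0 ± 15.0 FPKM (limma adjusted p = 0.0411). It was the 1 of 24 genes of bile acid synthesis and transport that fell over all genes, and 6 fell adjusted over the list alone; the median was -0.16 (camera adjusted p = 0.0424; adjusted p = 0.354 with an estimated correlation), and the call was lost without PBS replicate 3 (adjusted p = 0.135) or HA replicate 2 (adjusted p = 0.164). It was also lost with a filter at a mean of 1 FPKM (adjusted p = 0.0751) and with a replicate block (adjusted p = 0.0800). The median was -0.28 without HA replicate 1 and without HA replicate 2, -0.09 after median centring, -0.10 with voom on median-ratio depths and -0.07 outside Alb. Of 17 markers of pericentral hepatocytes, the cells around the central vein, 16 had a negative log2 fold change. Oat fell over all genes, from 1319 ± 279 to 466 ± 113 FPKM, and 11 fell adjusted over the list alone, among them Lect2, Rhbg and Glul, with a median of -0.58 (adjusted p = 2.72e-06; adjusted p = 0.264 with an estimated correlation). Periportal markers were higher as a list of 16, with a median of 0.15 (adjusted p = 0.00561; adjusted p = 0.423 with an estimated correlation); 0 passed over all genes, and Ctsc and Cdh1 rose adjusted over the list alone. Without HA replicate 2 their median was -0.02 and the call was lost (adjusted p = 0.396). The median was 0.07 without PBS replicate 3, 0.32 without HA replicate 1 and 0.30 without HA replicate 3. Of 21 male-biased liver genes, 3 fell (Mup12, Mup21 and Cyp4a12a) and 1 rose (Serpina1e), and adjusted over the list alone 11 fell and 2 rose, with a median of -0.67 (adjusted p = 0.00643; adjusted p = 0.326 with an estimated correlation). The male-biased median was -1.02 with voom on recovered fragments, -0.98 with voom on median-ratio depths and -0.95 with a pseudocount of 0.1. Female-biased genes did not pass (adjusted p = 0.527). Of 22 autophagy and lysosome genes 0 passed over all genes, and Gabarapl1 and Atg7 fell adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00249; adjusted p = 0.354 with an estimated correlation).

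Transcripts of the acute phase were higher as a list in camera with a preset correlation. Of 24 measured members, Mt2 and Itih3 rose and Hamp fell over all genes, and adjusted over the list alone 8 rose and 1 fell. Itih3 went from 243 ± 49.3 to 507 ± 53.5 FPKM (limma adjusted p = 0.0453), and Mt1 was 78.7 ± 13.8 and 227 ± 75.7 FPKM, past the threshold adjusted over the list alone. The median was 0.58 (camera adjusted p = 2.49e-07; adjusted p = 0.264 with an estimated correlation), and 0.33 without HA replicate 1, with the call kept (adjusted p = 1.46e-05). Hepatocyte identity genes did not pass (adjusted p = 0.271), with a median of -0.14, a mean of 0.01 and a test direction that was up. Adjusted over that list alone 5 were higher, among them Apoa1 and Alb, and 1, Apoa2, was lower. Alb was 41430 ± 5692 FPKM with PBS and 67630 ± 5860 FPKM with HA.

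The lists of red blood cells and of several cell types other than hepatocytes were higher in camera with a preset correlation, and of these only red blood cells had members past the threshold over all genes. Of 6 measured red blood cell genes, Hba-a1, Hba-a2 and Hbb-bt rose over all genes and 5 rose adjusted over the list alone, with a median of 1.84 (camera adjusted p = 8.34e-07; adjusted p = 0.264 with an estimated correlation). The list of macrophages and Kupffer cells was higher, with a median of 0.37 over 20 genes (adjusted p = 1.92e-06; adjusted p = 0.340 with an estimated correlation); 0 passed over all genes, and Cd9 and Marco rose adjusted over the list alone. Its median was 0.20 without HA replicate 3 and 0.56 without HA replicate 2. Stellate cell and fibrosis genes had a median of 0.23 over 22 genes (adjusted p = 0.000645; adjusted p = 0.411 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone, and Lum had the smallest p. The median was 0.05 without HA replicate 2 (adjusted p = 0.0171) and 0.14 without PBS replicate 3 (adjusted p = 0.00642). Inflammatory cytokines and chemokines had a median of 0.16 over 14 genes (adjusted p = 0.0144; adjusted p = 0.264 with an estimated correlation; adjusted p = 0.0708 without HA replicate 3 and 0.0596 outside Alb), 0.10 without PBS replicate 1 and 0.41 without HA replicate 2. The cytokine median was 0.09 with no filter, 0.26 with voom on recovered fragments and 0.31 with voom on median-ratio depths. Icam1 led that list at 2.83 ± 0.779 and 4.66 ± 0.438 FPKM, and 0 members passed by either adjustment. Cholangiocyte markers had a median of 0.19 over 7 genes (adjusted p = 0.00550; adjusted p = 0.388 with an estimated correlation; adjusted p = 0.0565 without HA replicate 2), with 0 past the threshold by either adjustment. The median was 0.06 without HA replicate 2, 0.46 without HA replicate 1, 0.44 with a pseudocount of 0.1 and 0.56 with voom on median-ratio depths. Lymphocyte markers had a median of 0.29 over 5 genes (adjusted p = 0.0214; adjusted p = 0.388 with an estimated correlation), lost without HA replicate 2 (median 0.09, adjusted p = 0.132) or 3 (adjusted p = 0.0636), with voom on median-ratio depths (median 0.80, adjusted p = 0.0734) and outside Alb (median 0.34, adjusted p = 0.0596). The lymphocyte median was 0.06 with no filter and 0.67 with a pseudocount of 0.1, and Jchain rose adjusted over the list alone. S100a8 and S100a9, the 2 measured neutrophil genes, both rose adjusted over the list alone, and that list was too short to test. Genes of other tissues below the filter on low values were uneven between libraries. The 11 exocrine pancreas genes summed to 192 fragments in HA replicate 2. They summed to 64 in PBS replicate 2, 74 in HA replicate 3 and 2 to 13 in the other 3 libraries. The 4 adipocyte genes below the filter summed to 115 fragments in PBS replicate 1 and 77 in HA replicate 2. The other 4 libraries held 0 to 3.

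**Figure D3:**
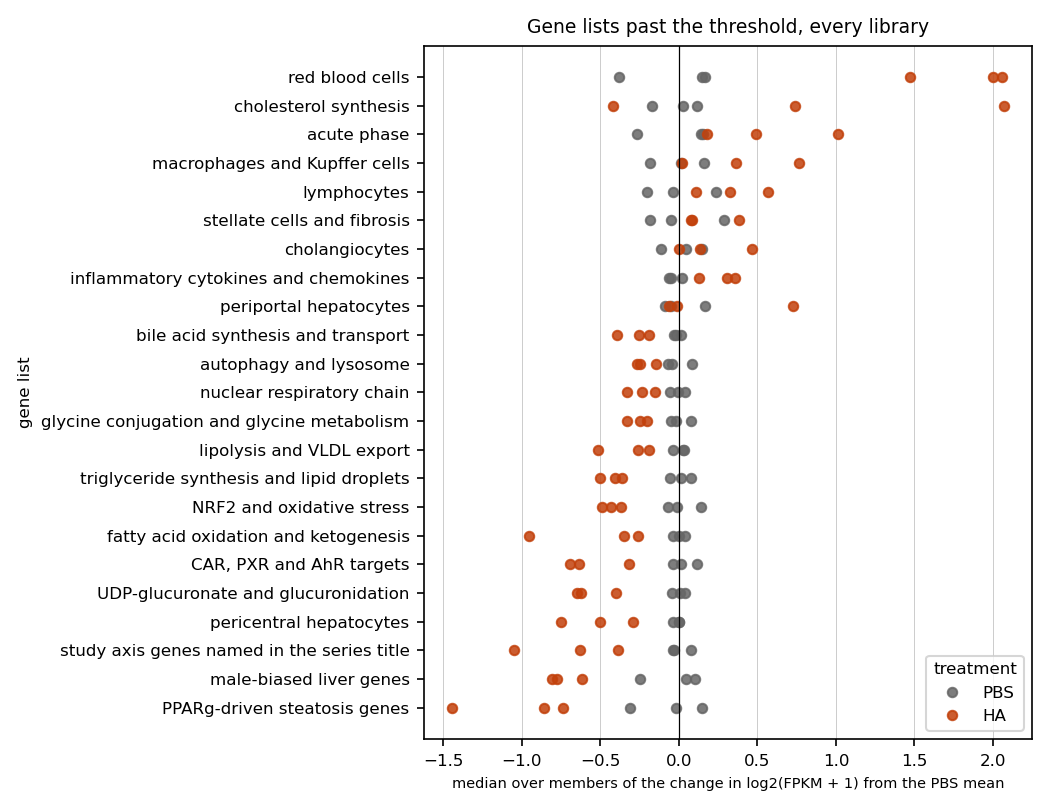
The 23 gene lists past the threshold in camera with a preset correlation, 1 row per list; each point is the median over members, in 1 library, of the difference in log2(FPKM + 1) from the mean of the PBS libraries, grey for PBS and orange for HA. All 3 HA points of red blood cells lie above and all 3 of PPARg-driven steatosis genes below the PBS points of the list, and the HA libraries spread widely for cholesterol synthesis, from -0.42 to 2.07.

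Of the 38 lists tested, 9 were higher and 14 lower with HA, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. The 14 include the list of the title genes, which comes from the study itself. Among lists that did not pass were interferon response, endothelium, adipocytes, the cell cycle, the circadian clock, glycolysis, gluconeogenesis, the unfolded protein response, immediate early and heat shock genes and ribosomal proteins, with adjusted p from 0.0755 to 0.805. Of the 15 lists that did not pass, 8 did without 1 library, de novo lipogenesis and the mitochondrially encoded transcripts among them. Interferon response was lower without PBS replicate 3 (adjusted p = 0.0241), and immediate early and heat shock genes without PBS replicate 2 (adjusted p = 0.0462). Adipocytes were lower without HA replicate 2 (adjusted p = 0.0120), and the unfolded protein response without HA replicate 1 (adjusted p = 0.00425). Without PBS replicate 3 or HA replicate 1, endothelium (adjusted p = 0.00833 and 0.0412) and ribosomal proteins (adjusted p = 0.0200 and 0.00927) were higher. In the heat shock list Hspa1b fell over all genes, from 5.13 ± 0.804 to 1.71 ± 0.613 FPKM, and adjusted over the list alone 4 fell and 1 rose. The median, mean and test differed in sign for gluconeogenesis, glycolysis, endothelium, female-biased genes, the circadian clock and the cell cycle. Outside Alb the medians of glycine metabolism, autophagy and the nuclear respiratory chain were smaller, at -0.165, -0.123 and -0.155, and that of periportal markers larger, at 0.233, with all 4 calls kept. The list of exocrine pancreas had 1 measured member and was not tested.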

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

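The tests of explanations in this part were chosen after the result was seen. Fixed lists were also summed over their members below the filter on low values, in 23 lists that had any, by a rule set after the data were seen: groups that do not overlap and differ at least 3-fold. One list met it. The red blood cell gene Slc4a1, the anion exchanger of the red cell membrane, which the comparisons above do not use, held 2, 10 and 11 fragments in PBS replicates 1 to 3 and 199, 59 and 90 in HA replicates 1 to 3, a 15.2-fold higher share with HA (9.97-fold without HA replicate 1). Chance alone keeps 3 values apart from 3 others in 10% of cases, and 25.6% of the genes tested here were apart. With 23 lists searched, groups that do not overlap are thus weak evidence alone. The list of red blood cells had already passed above on its measured members.

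The pattern is that red cell transcripts were higher with HA, with globin fragments 4.10-fold higher. More residual blood of an unchanged makeup would raise all red cell genes alike. Of the list fixed beforehand, red cell precursors express Slc4a1 and Ahsp (named, like Alas2, outside the rule for named genes, after their values were seen). The ratio of their summed fragments to globin fragments was 0.0449 to 0.187% with PBS and 0.233 to 1.55% with HA. It was 5.49-fold higher on average. HA replicate 1 carried most of this, with 2.30-fold left without it. The lowest HA ratio rested on 70 fragments (95% counting interval 0.181 to 0.294%) and the highest PBS ratio on 13 (0.0995 to 0.319%), so these intervals overlapped. Alas2, which precursors also express, was left out of the ratio above. It was 40.8 ± 4.59 FPKM with PBS and 35.1 ± 1.29 FPKM with HA and passed by neither adjustment. Alas2 thus did not rise with the globins, though more blood or more precursors would each raise it. Together the 3 platelet genes were 1.53-fold higher. More residual blood and more immature red cells thus cannot be told apart here. The fragments of Slc4a1 and Ahsp are few, and Alas2 goes with neither explanation. Whether immature red cells, if present, divide in the liver itself or arrive in its blood cannot be told apart either: the median log2 change of 13 cell cycle genes was -0.10, in which a small share of dividing cells would stay hidden. The 12 cell cycle genes below the filter summed to 345, 315 and 269 fragments in PBS replicates 1 to 3 and 1015, 220 and 292 in HA replicates 1 to 3, higher in HA replicate 1 alone.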

How the results depend on the processing

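The cause of each change below was not tested unless the setting itself shows it. Higher and lower genes numbered 31 and 55. They were 16 and 26 with an absolute log2 fold change above 1, 7 and 10 with no filter (16638 genes tested), 36 and 32 after median centring, and 30 and 64 with a filter at a mean of 1 FPKM. Chosen after seeing the data, voom on recovered fragments gave 23 and 37, voom with median-ratio depths 28 and 19, FPKM outside Alb 33 and 24, and limma with no trend 33 and 65. Leaving out 1 library, which also leaves fewer samples, gave 1 to 46 higher and 4 to 69 lower; all 86 genes kept their direction in each of these settings that tested them. Cd36 passed at -1.03 and kept its direction throughout, but did not pass with no filter (-1.03), with voom on median-ratio depths (-0.99) or outside Alb (-0.95); without 1 library it lay between -1.17 and -0.91. Ugdh and Foxk1 kept their direction and stayed short of the threshold in all settings. The count of gene lists was 23, 19 to 25 in all other settings and 0 with an estimated correlation; the filter at 1 FPKM left too few lymphocyte and cholangiocyte markers to test. The 18 genes named by size lost their call in 50 of 108 values without 1 library and in 31 of 162 under other settings, with none reversed; the lists lost theirs in 15 of 138 and 31 of 228.

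Same-numbered libraries did not deviate together (correlations -0.14, -0.12 and 0.18). With so few libraries this gives no sign of pairing but cannot exclude it, and no label says whether the numbers pair the samples. With a replicate block, 7 genes were higher and 9 lower, and Cd36 was at -1.03 (adjusted p = 0.118, against 0.0287 to 0.152 over its alternatives). DESeq2, voom on deposited counts, RLE and total-count scaling, and a comparison of both units, were planned for counts and were not run because the table held FPKM. Depth limits low genes: 5893 genes fell below the filter.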

Other observations

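All tests in this part were chosen, or their predictions written down, after the results were seen. The genes named here other than Hamp and Hamp2 lie outside the rule for named genes. Among iron genes other than hepcidin, 0 of 5 passed over all genes tested. Tfrc, the receptor that takes up transferrin, was 4.99 to 7.32 FPKM with PBS and 15.2 to 42.3 FPKM with HA (limma adjusted p = 0.0648), and Trf, which encodes transferrin, was higher in all 3 HA libraries (log2 fold change 0.57, adjusted p = 0.129). The ferritin gene Ftl1 was lower in all 3 HA libraries, at 1803 to 2292 FPKM against 3230 to 3537 FPKM (adjusted p = 0.0555), as was Fth1 (adjusted p = 0.219), while the iron exporter gene Slc40a1 overlapped between groups. Fgl1, a protein secreted by the liver, rose from 302 ± 51.7 to 868 ± 225 FPKM (n = 3 per group, adjusted p = 0.0424), and was named after its values were seen.

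Hepcidin transcripts were far lower with HA. Fragments shared between Hamp and its copy Hamp2 would leave their sum alike, but the sum was 118-fold lower with HA, which argues against them. A lower share of hepatocytes would lower their genes by about as much, but the median log2 change of 20 hepatocyte identity genes was -0.145 (SD between members 0.428; -0.0473 without HA replicate 1). Lower BMP-SMAD signalling, the main route that turns hepcidin on, may account for it as a hypothesis. The median log2 change of 7 other targets was -0.98, far short of the -7.63 of Hamp. Of the 7, 6 (Id1, Id2, Id3, Smad6, Smad7 and Atoh8) were lower in all 3 HA than in all 3 PBS libraries. Over all genes 0 of the 7 passed. Of all 10745 genes tested, 2059 were lower in the same way. Id1, Id2, Id3, Smad6 and Smad7 were highest in PBS replicate 1, the library with more adrenal and muscle transcripts. What would lower that signalling was not tested.

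PBS replicate 1 held more adrenal and muscle transcripts than the other 5 libraries. RNA of adjoining adrenal gland and muscle in that library may account for them. Of the listed genes whose values had not been seen when the lists were written, 8 of 8 detected (100%) were highest there. Detected genes had at least 10 fragments summed over the 6 libraries, so a gene high in any library could be kept. Genes with 0 fragments in the other libraries could reach that sum only through PBS replicate 1. A library of another tissue or of the other group is argued against by its correlations, at least 0.988 with the other PBS libraries and at most 0.982 with the HA libraries. Hsd3b1, Star and Cyp21a1 led the adrenal genes at 19.1, 14.0 and 13.3 FPKM, and Acta1 and Mb the muscle genes at 14.9 and 14.8 FPKM.

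The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 86 genes, 1 split of the 10 reached that number, and the highest of the others called 0. Each of the others has both treatments on both sides, so a treatment difference widens the spread within sides and lowers the calls. Those splits thus cannot show how many genes an unrelated grouping would call.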
